A study of Mus musculus with 2 samples.

How the data were processed

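Cells dissociated from 2 fresh tumors, a cystic and a tubular adenocarcinoma that arose from injected DP-DSCs, were encapsulated on the inDrop platform of 1CellBio and made into libraries with the TruDrop protocol, per the labels' protocols. The samples were grouped by tumor type from the labels, with 1 library per type. The submitters' processing notes name the mouse build mm10, the aligner STAR 2.7.3a, Partek and DESeq2 3.5, without saying which step each served. Cell filters, doublet treatment, the clustering method, cluster sizes and depth per cell are not given in the sources used here. The name of the deposited table speaks of a fixed number of cells each, without saying whether of each tumor or each cluster, and was not used.

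The values are from 1 table of the authors' own comparisons. For each of 11 clusters it gives gene names, a linear fold (a ratio, per the file headers) and a p-value (per the file headers), as the authors deposited them. The genes of a cluster are ordered by the deposited p-value, and every deposited fold exceeds 1.5, so falling and weakly raised genes are not seen. The reference of the fold is not written in the table; a cluster against the remaining cells is the usual meaning. The test behind the p-value and any adjustment of it are not stated. It was made over cells, which are not replicates, and clusters drawn from expression make such a p too small, so the deposited p was used to filter genes and is not printed. Deposited folds can also be very large for genes detected in few cells, since the level in the reference is then close to 0. The table holds 0 columns of per-sample values, and tumor types could not be compared.

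A gene was called raised in a cluster at a deposited fold of at least 2 and a deposited p of at most 0.05. The gene lists were fixed before the data were examined: 45 lists, of which 23 mark cell types and 22 pathways or processes. For a table that lists only filtered genes, the rule fixed beforehand was a one-sided exact hypergeometric test of the number of members listed in a cluster, against the 18319 genes named anywhere in the table, with Benjamini-Hochberg adjustment over the 429 pairs of the 39 lists with at least 3 named members and the 11 clusters. A list had a call at an adjusted p of at most 0.05. Such a p compares genes, not animals, and describes these libraries. Being listed does not need a small deposited p, so the number of raised members was tested in the same way, a test added after the data were seen.

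Genes were named by a rule fixed beforehand: the 5 largest folds among raised genes of each cluster, leaving out ribosomal, mitochondrially encoded and unnamed predicted genes; the 3 members of largest fold of each list with a call; and 14 genes in every cluster. Some genes that this rule takes are not reported here. Chosen after values were seen were the genes that come first in a cluster by p, the members named for lists that passed on raised members alone, and further list members given beside those of the rule. A cluster was called like a cell type only from the fixed marker lists. Cluster 10 was named from its neutrophil genes, though the macrophage and the T and NK lists also had calls there. Those calls held on listed and on raised members. Cluster 8 was left unnamed because its leading dendritic genes had larger folds than its macrophage genes while a macrophage gene came first by p. Clusters 1, 2, 5 and 7 kept their numbers. Either no cell type list led them on both counts, or their leading genes were of another kind.

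Clusters were compared by the Pearson and Spearman correlation of log2 folds over the genes listed in both, and by the number of shared raised genes against the product of the list sizes divided by 18319. Simulated values came from 11 clusters of 180 cells and 6000 genes with no shared raised genes; they lay far from the observed ones and were not used as a chance level. Gene coordinates and types are those of GENCODE M21 on GRCm38 (mm10), matched by symbol; 17925 of the 18319 names (97.8%) matched, and positions are 1-based.

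The list test was tested on simulated tables with the real cluster sizes. Lists of 10 members planted at a 95% chance of being listed were called in 98.2% of cases over all clusters and in 87.5% in cluster 9, the largest, and lists with no planted members in 0.234%. The lists tested had 4 to 20 named members, and no size other than 10 was simulated. Unplanted lists and listed genes were drawn at random, as the test itself assumes. Their rate of calls therefore says nothing about lists of genes that are expressed together. Several lists with a call had a smaller share listed than 95%, and the rate for planted lists does not apply to them. In cluster 9 the goblet list, with 6 of 6 members listed, had an adjusted p of 0.0442 (exact hypergeometric test). Shorter lists therefore had little or no room for a call there. The alternatives fixed beforehand were fold thresholds of 1.5 and 3, a p of at most 0.001, Benjamini-Hochberg adjustment of the deposited p over the listed genes, leaving out ribosomal and predicted genes, leaving out each list's largest member, and percentiles of a list's median or mean log2 fold among 10000 random lists, drawn with replacement. In the percentiles an unlisted gene was set to a fold of 1.5 and a list had a call at the percentile 99 or above; matched random lists had the same largest fold in the other clusters, in 20 bins. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.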

Results

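Tumors that grew from injected mouse dysplastic stem cells were profiled by single-cell RNA sequencing on the inDrop platform, which captures single cells with barcoded beads in droplets. The injected cells carry the name DP-DSC in the labels. There were 2 libraries from female mice of the NuJ strain, 1 from a cystic adenocarcinoma taken 10 weeks after injection and 1 from a tubular adenocarcinoma taken 13 weeks after injection. The values analysed were those of a single table of the authors' own comparisons, which gives for each of 11 cell clusters the genes with a linear fold above 1.5, each with a p-value. The table names 18319 genes and lists 46855 pairs of a gene and a cluster. Its columns carry cluster numbers and no tumor type. The reference of each fold is not written in it, and the number of cells per cluster and the transcripts counted per cell are not given in the sources used here, so the depth behind each fold is unknown. The table's name speaks of a fixed number of cells each, but not whether this is per tumor or per cluster. With 1 library per tumor type there are no replicates, and no value below has an error across animals.

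Throughout, a gene is called listed in a cluster when the table gives it there, and raised when its deposited fold is at least 2 with a deposited p of at most 0.05. The largest folds of a cluster are given for raised genes with a name, leaving out ribosomal and predicted genes, some of which had larger folds. In clusters 1 to 4 and 6 to 10, none of the 5 such genes of largest fold was among the first 5 by p. The first question the table answers is which cell types the clusters resemble. Of the 18319 genes, 14289 were raised in at least 1 cluster, 9333 in exactly 1 and 0 in 5 or more. The number of raised genes ran from 333 in cluster 1 to 4871 in cluster 9. Clusters 4, 6 and 11 had 3402, 3713 and 3112 raised genes, against 529 in cluster 2, 733 in cluster 3, 792 in cluster 5, 626 in cluster 7, 1166 in cluster 8 and 897 in cluster 10. The share of listed genes with a deposited p of at most 0.05 was 97.3% in cluster 9 and 16.0% in cluster 3. Cluster 3 therefore had 5474 listed genes but few raised ones, and its count depends most on the p: 4025 of its genes had a fold of at least 2 whatever the p.

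**Figure D1:**
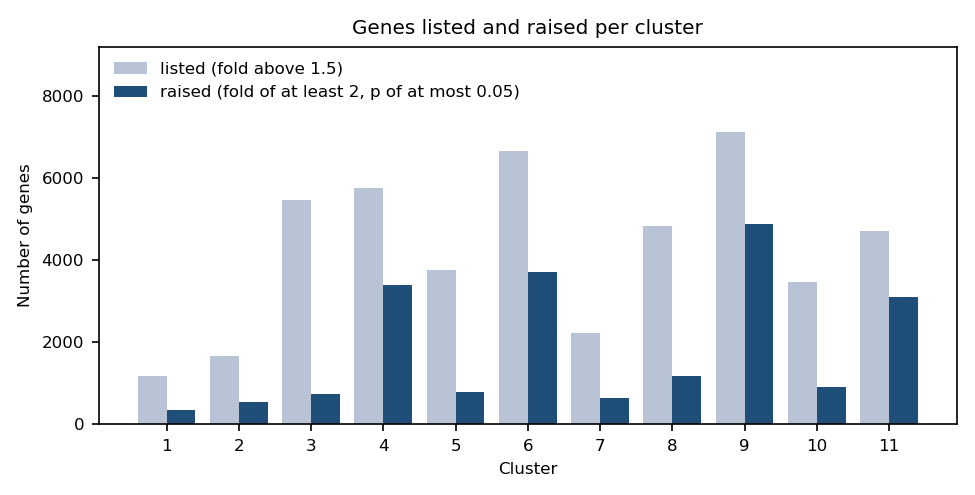
Number of genes (vertical axis) in each of the 11 clusters (horizontal axis). Pale bars count the genes listed with a fold above 1.5 and dark bars the genes raised, from 333 in cluster 1 to 4871 in cluster 9.

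Fixed gene lists were compared with the clusters by the number of members listed. Of 429 pairs of a list and a cluster, 37 had more members listed than chance gives (one-sided exact hypergeometric test, Benjamini-Hochberg adjusted p of at most 0.05). When only raised members were counted, 33 pairs passed and 22 of the 37 were among them. The call held under every alternative tried for 9 of the 37: erythroid in cluster 2, macrophage in clusters 4 and 8, surface mucous in cluster 6, dendritic in cluster 8, neutrophil and T and NK in cluster 10, and fibroblast and G2/M phase in cluster 11. At the other end, 10 of the 37 held under at most 2 of the alternatives: ribosomal in cluster 3, interferon response in clusters 4 and 11, general epithelium in clusters 5, 6 and 9, mucous neck in cluster 6, S phase in cluster 6, goblet in cluster 9 and unfolded protein response in cluster 10. Calls kept under 3 or 4 were erythroid in cluster 1, surface mucous and general epithelium in cluster 3, basement membrane in clusters 5 and 9, YAP and fetal-like in cluster 6, ribosomal in cluster 7, chemokines in cluster 8, MHC class II in cluster 10 and epithelial-mesenchymal transition in cluster 11. The rest were kept under 5 to 7.

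**Figure D2:**
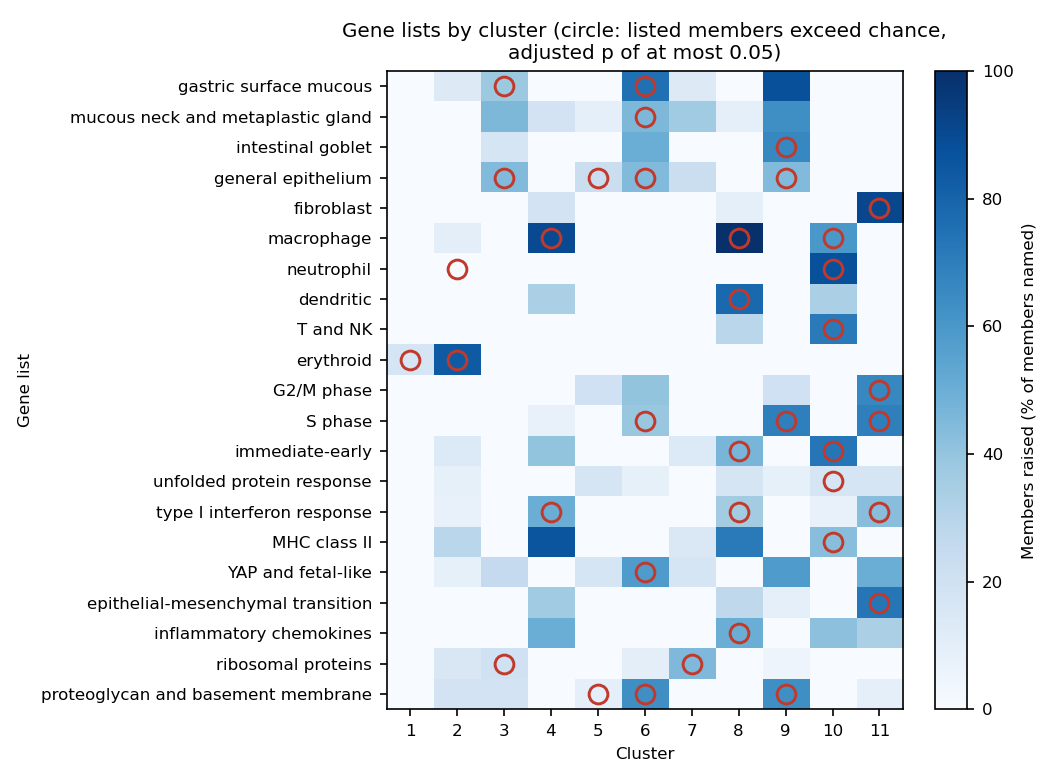
Gene lists (vertical axis) by cluster (horizontal axis), for the lists with a call in at least 1 cluster. Colour gives the percentage of named members that were raised, and a red circle marks the 37 pairs whose number of listed members exceeded chance at an adjusted p of at most 0.05.

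Cluster 4 was macrophage-like, and cluster 8 held macrophage and dendritic cell genes together and was left without a single name. Cathepsin S (Ctss), a lysosomal protease of antigen-presenting cells, came first in cluster 4 by p with a fold of 5.75 in the authors' deposited table, and lysozyme (Lyz2) came first in cluster 8 with a fold of 5.69. Ctss lies on chromosome 3 from 95526786 to 95556403 and Lyz2 on chromosome 10 from 117277331 to 117282321. Of 10 macrophage genes, 10 were listed and 9 raised in cluster 4 (adjusted p = 0.000648, exact hypergeometric test), and all 10 were listed and raised in cluster 8 (adjusted p = 0.000142). The lysosomal glycoprotein Cd68, the complement chain C1qc and Lyz2 led the list in cluster 4, with folds of 8.90, 7.47 and 6.95 in the authors' deposited table. In cluster 8 the complement chain C1qb, Lyz2 and Cd68 led it, at 5.88, 5.69 and 5.33 in the authors' deposited table.

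The largest folds of cluster 4 belonged to the transmembrane glycoprotein Gpnmb (76.7), the transcription factor Egr2 (64.4), the lectin Cd209b (51.3), Fam169b (44.6) and the glucuronosyltransferase Ugt1a2 (44.4) in the authors' deposited table. Type I interferon response genes had 10 of 14 members listed in cluster 4 (adjusted p = 0.0394) and 7 raised, led in the authors' deposited table by Ifit2 at 7.76, Oasl1 at 5.36 and Ifit1 at 4.49. That interferon call ended when raised members were counted (adjusted p = 0.0885). MHC class II genes, which present peptides to CD4 T cells, had 6 of 7 members listed in cluster 4 (adjusted p = 0.0544). All 6 were raised (adjusted p = 0.00516), and H2-Eb1 was highest at 20.0045 in the authors' deposited table.

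The leading dendritic cell genes of cluster 8 had larger folds than its macrophage genes. The dendritic list had 8 of 9 members listed (adjusted p = 0.00502) and 7 raised, H2-Ab1 and Cd74 of the MHC class II list among them. The lectin Clec9a, a receptor of cross-presenting dendritic cells, had a fold of 74.6 in the authors' deposited table, and the cytokine receptor Flt3 and the lectin Cd209a had 42.5 and 7.23. Clec9a was also among the 5 largest folds of the cluster in the authors' deposited table, after Slc24a1 (169.0), Adal (121.1) and Dnaaf4 (91.1) and before Amigo1 (73.1). Immediate-early genes, which respond within minutes to stimulation or handling, had 12 of 15 members listed (adjusted p = 0.00102) and 7 raised, led in the authors' deposited table by Nr4a1 at 5.61, Klf2 at 4.92 and Atf3 at 3.83. Interferon response genes had 10 of 14 listed (adjusted p = 0.0121) and 5 raised, with the transcription factor Irf7 at 11.996 in the authors' deposited table. Rtp4 at 4.69 and Ifit1 at 4.64 in the authors' deposited table had a p above 0.05 there. Inflammatory chemokines had 8 of 12 listed (adjusted p = 0.0484, kept under 4 of 8 alternatives) and 6 raised, with Cxcl10 at 13.5 and Ccl2 at 3.75 in the authors' deposited table; Tnf, at 3.22, was not raised. The MHC class II list had 5 of 7 members listed (adjusted p = 0.148), all 5 of them raised (adjusted p = 0.000698).

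Cluster 10 was neutrophil-like. By p it began with the cytokine Il1b, the chemokine Ccl3 and the calcium-binding protein S100a9, whose folds were 7.47, 33.9 and 18.9 in the authors' deposited table. Il1b lies on chromosome 2 from 129364570 to 129371139. Of 8 neutrophil genes 7 were listed and raised (adjusted p = 0.00206, exact hypergeometric test). The largest were G0s2, a lipase inhibitor, at 117.8, the G-CSF receptor Csf3r at 57.2 and the chemokine receptor Cxcr2 at 53.0 in the authors' deposited table. Immediate-early genes had 13 of 15 listed and 11 raised (adjusted p = 5.99e-06), and their leaders Egr1, Zfp36 and Ier3 had folds of 15.6, 11.2 and 11.2 in the authors' deposited table. The macrophage list had 10 of 10 members listed (adjusted p = 6.87e-06) and 6 raised (adjusted p = 0.000115, exact hypergeometric test), so its call also held on raised members. Its members of largest fold in the authors' deposited table were Adgre1 at 7.84, C1qa at 4.60 and C1qb at 4.36, of which C1qa was raised.

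Markers of T and NK cells had 6 of 7 members listed in cluster 10 (adjusted p = 0.00724). Of these, 5 were raised, namely Cd4, Cd3e, Gzma, Ncr1 and Nkg7. The co-receptor Cd4 had a fold of 110.7, the T cell receptor subunit Cd3e 25.9 and the NK receptor Klrb1c 26.4 in the authors' deposited table, and Klrb1c was not raised. MHC class II genes had 5 of 7 listed and 3 raised (adjusted p = 0.0442, kept under 3 of 8 alternatives), with Cd74 at 4.29 and H2-Ab1 at 3.95 in the authors' deposited table. H2-Eb1, at 4.06 in the authors' deposited table, was not raised. Genes of the unfolded protein response had 7 of 12 listed (adjusted p = 0.0399) and 2 raised, Ddit3 at 11.1 and Dnajb9 at 3.75 in the authors' deposited table. Its members Trib3 at 15.3 and Xbp1 at 5.22 in the authors' deposited table were not raised, and the call ended on raised members (adjusted p = 0.563). Chemokines had 6 of 12 listed (adjusted p = 0.141) and 5 raised (adjusted p = 0.00373), led in the authors' deposited table by Cxcl3 at 69.8, Tnf at 17.3 and Cxcl2 at 14.7. The 5 largest folds of cluster 10 in the authors' deposited table were those of Trpc5os (426.8), the chitinase-like Chil1 (253.0), the sodium pump subunit Atp1a4 (231.7), the histamine receptor Hrh2 (225.8) and Spatc1 (215.8).

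Cluster 11 was fibroblast-like. The hyaluronan-binding protein Tnfaip6 (1017), the collagen chain Col5a3 (851.2), the protease inhibitors Serpina3n (709.9) and Serpinb2 (530.0), and fibrillin-1 (Fbn1, 503.7) had its largest folds in the authors' deposited table. Tnfaip6 lies on chromosome 2 from 52038009 to 52056686. Of 11 fibroblast genes 10 were listed and raised (adjusted p = 0.000648, exact hypergeometric test), led by the collagen I chains Col1a2 at 343.5 and Col1a1 at 312.2 and the growth factor receptor Pdgfra at 284.0 in the authors' deposited table. Genes of the epithelial-mesenchymal transition had 8 of 11 listed and raised (adjusted p = 0.0248, kept under 4 of 8 alternatives, with a matched percentile of 93.78). The matricellular protein Sparc, which the fibroblast list also holds, and the transcription factors Snai1 and Twist1 were at 84.6, 28.3 and 24.1 in the authors' deposited table.

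Cell-cycle genes also stood out in cluster 11. The G2/M list had 12 of 15 members listed and 10 raised (adjusted p = 0.000897), with topoisomerase Top2a at 43.1, survivin (Birc5) at 18.2 and Nusap1 at 16.2 in the authors' deposited table. Among matched random lists the G2/M list also passed 99 in clusters 5, 6 and 7, at 99.8, 99.71 and 99.59. It had no call there on listed or raised members. The S phase list had 10 of 13 listed and 9 raised (adjusted p = 0.00502), led in the authors' deposited table by Uhrf1 at 15.3, thymidylate synthase (Tyms) at 7.83 and Hells at 4.71. Interferon response genes had 9 of 14 listed (adjusted p = 0.0399) and 6 raised, with Ifit3 at 83.3, Ifit1 at 11.8 and Mx1 at 6.79 in the authors' deposited table. The interferon call ended on raised members (adjusted p = 0.182).

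Clusters 3, 6 and 9 resembled gastric epithelium. By p, the intermediate filament gene Krt20 came first in cluster 9 and Krt18 in cluster 6, with folds of 3.83 and 2.34 in the authors' deposited table, and the secreted chaperone clusterin (Clu) came first in cluster 3 with 2.40. Krt20 lies on chromosome 11 from 99428403 to 99438150 and Krt18 on chromosome 15 from 102028180 to 102032027. Genes of the gastric surface mucous cell had 8 of 8 members listed and 6 raised in cluster 6 (adjusted p = 0.00729, exact hypergeometric test) and 7 of 8 listed and 3 raised in cluster 3 (adjusted p = 0.0224). In cluster 9, 7 of 8 were listed, which missed the threshold (adjusted p = 0.0746), and all 7 were raised (adjusted p = 0.0103). The secreted gastrokines Gkn2 and Gkn1 and the mucin-like gene Mucl3 were at 10.8, 4.82 and 5.46 in cluster 6 and at 5.60, 5.94 and 7.34 in cluster 9 in the authors' deposited table. In cluster 3 the largest folds of that list in the authors' deposited table were those of Gkn1 (4.01) and Vsig1 (3.66), neither raised, and the protease cathepsin E (Ctse, 3.20), which was raised.

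General epithelial genes were listed beyond chance in clusters 3, 5, 6 and 9, with 7, 6, 8 and 8 of 9 members and adjusted p of 0.0484, 0.0442, 0.0307 and 0.0429. On raised members the call remained in cluster 3 (adjusted p = 0.00557) and ended in clusters 5, 6 and 9 (adjusted p of 0.353, 0.484 and 0.834). In cluster 3 it was kept under 3 of 8 alternatives, with percentiles of 98.3 for the mean and 83.89 when matched. Their members of largest fold in the authors' deposited table included the tight-junction gene Cldn4 at 16.3 in cluster 3, where it was not raised, and at 2.76 in cluster 9, and Krt19 at 2.94 in cluster 6 and 2.53 in cluster 9. Cldn3 and Elf3 followed in cluster 3 with 4.80 and 4.07, and Cldn3 and Krt18 in cluster 6 with 2.92 and 2.34, in the authors' deposited table; Elf3 was not raised in cluster 3. Krt18 was at 2.04 in cluster 9 in the authors' deposited table. In cluster 5 the adhesion gene Cdh1 was raised at 3.94 in the authors' deposited table, while Cldn3 at 3.76 and Elf3 at 3.41 were not raised.

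Genes of the basement membrane and its receptors had 10 of 11 members listed in cluster 6 (adjusted p = 0.00729) and in cluster 9 (adjusted p = 0.0121), and 7 raised in each. The laminin chains Lamb3 and Lama3 were at 4.97 and 3.59 in cluster 6, and the integrin Itga3 and the collagen chain Col4a1 were at 3.15 and 3.09 in cluster 9, in the authors' deposited table. On raised members the call remained in cluster 6 (adjusted p = 0.0294) and ended in cluster 9 (adjusted p = 0.108). S phase genes had 10 of 13 listed in cluster 6 (adjusted p = 0.0442) and 11 of 13 in cluster 9 (adjusted p = 0.0205), with 5 and 9 raised, and the call in cluster 6 held under 0 of 8 alternatives, with an adjusted p of 0.52 on raised members. The replication genes Rrm2, Tyms and Mcm2 led in cluster 6 at 6.04, 5.92 and 4.47, and Hells, Mcm5 and Uhrf1 in cluster 9 at 6.34, 4.94 and 4.40, in the authors' deposited table.

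YAP target and fetal-like genes had 10 of 12 listed and 7 raised in cluster 6 (adjusted p = 0.0224), a call that ended on raised members (adjusted p = 0.0532). Cluster 9 had 9 of 12 listed and also 7 raised (adjusted p = 0.124, and 0.179 on raised members). Against random lists the median of these genes lay at the percentile 99.62 in cluster 6 and 99.33 in cluster 9, and the difference between the clusters was not tested. In cluster 6 the cytokine Il33 was at 5.84 in the authors' deposited table, and Amotl2 at 5.27 was not raised. Mucous neck and metaplastic gland genes had 9 of 11 listed and 5 raised in cluster 6 (adjusted p = 0.0399, and 0.353 on raised members), led in the authors' deposited table by the immunoglobulin receptor Pigr at 9.29, the trefoil factor Tff2 at 3.66 and Gkn3 at 2.96. Cluster 9 also had 9 of 11 listed, and 7 raised (adjusted p = 0.0538, and 0.108 on raised members). The same list had 5 of 11 raised in cluster 3 (adjusted p = 0.00117 on raised members and 0.172 on listed ones), with the chloride channel Cftr at 7.54 and the water channel Aqp5 at 3.69 in the authors' deposited table. Intestinal goblet genes had 6 of 6 listed and 4 raised in cluster 9 (adjusted p = 0.0442, and 0.322 on raised members), and 4 of 6 listed and 3 raised in cluster 6 (adjusted p = 0.62, and 0.52 on raised members). Against random lists they lay higher in cluster 6, at percentiles of 99.88 (median), 99.24 (mean) and 99.95 (matched), than in cluster 9, at 97.6, 98.82 and 99.91. In cluster 9 Fcgbp was at 8.37, Spink4 at 4.68 and Clca1, which was not raised, at 2.696 in the authors' deposited table.

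The largest folds in cluster 3 were those of Jakmip1 (226.0), Zfp58 (157.1), Spef2 (105.5), Zfp28 (58.7) and Psors1c2 (58.1) in the authors' deposited table. By p they stood at positions 122 to 599 of its 5474 listed genes. In cluster 6 they were the adenylate kinase Ak9 (87.0), the proton pump subunit Atp6v1g2 (56.5), Sult5a1 (39.3), Fam83h (37.9) and the keratin Krt4 (37.9) in the authors' deposited table. For cluster 9 the authors' deposited table gave the urinary protein Mup20 (45.0), Fhl3 (38.0), Slco5a1 (31.8), Zscan25 (28.8) and Sag (27.8).

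Clusters 1, 2, 5 and 7 were left without a cell type name. Ribosomal protein genes had 14 of 20 members listed and 9 raised in cluster 7 (adjusted p = 1.14e-06, exact hypergeometric test), among them Rplp2 at 5.42, Rpl18 at 2.99 and Rpl10 at 2.43 in the authors' deposited table. Of its raised genes with an annotation, 17.0% were pseudogenes, against 2.67% in cluster 9 and 8.64% in cluster 3, the next highest. Ribosomal protein genes have many near-identical pseudogene copies, so their values are uncertain. On raised members cluster 7 also passed for nuclear-encoded oxidative phosphorylation genes (5 of 15, adjusted p = 0.00247), mucous neck genes (4 of 11, adjusted p = 0.00686) and glutathione genes (4 of 11, adjusted p = 0.00686), none of which passed on listed members. The respiratory chain gene Ndufa4 was at 8.93, the secreted protein Wfdc2 at 3.75 and the glutathione transferase Gsta4 at 3.60 in the authors' deposited table. Its largest folds in the authors' deposited table were those of Vwce (494.3), the histone gene H3c4 (489.2), Fam167b (351.6), Nat8l (349.2) and Oip5 (270.8). The ribosomal list had 13 of 20 listed and 4 raised in cluster 3 (adjusted p = 0.0224, and 0.088 on raised members), with Rpl3 at 2.80, Rps18 at 2.75 and Rps2 at 2.39 in the authors' deposited table. Of the first 100 genes by deposited p, 41 had ribosomal names in cluster 7, 44 in cluster 3 and 26 in cluster 6. Names were matched at their start only, so these counts take in pseudogenes.

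By fold, cluster 5 was led by mast cell proteases. Tpsb2, Tpsab1 and Cpa3 had folds of 403.5, 203.0 and 177.7 in the authors' deposited table, followed by Slc5a9 at 123.5 and Zfp518a at 107.8. The tryptase genes Tpsb2 and Tpsab1 are close copies, so their values are uncertain. The mast cell list had 4 of 6 members listed (adjusted p = 0.164) and 3 raised (adjusted p = 0.0224 on raised members). Basement membrane genes had 9 of 11 listed in cluster 5 (adjusted p = 0.00102), and 1 of them was raised, so the call ended on raised members (adjusted p = 1). Its leaders Itga2 at 6.47, Col4a2 at 6.15 and Lama3 at 5.92 in the authors' deposited table each had a p above 0.05.

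Red cell genes stood out in clusters 1 and 2. In cluster 2, 5 of 6 erythroid genes were listed and raised (adjusted p = 0.00132), led in the authors' deposited table by the heme synthesis enzyme Alas2 at 11.8 and the globins Hbb-bs at 10.0 and Hba-a1 at 9.20. In cluster 1 all 6 were listed (adjusted p = 6.87e-06) but 1 was raised, the anion exchanger Slc4a1 at 31.7 in the authors' deposited table, and the call ended on raised members (adjusted p = 0.52). The globins Hbb-bt and Hba-a2 were at 2.55 and 2.37 in cluster 1 in the authors' deposited table, with a p above 0.05. The globin genes come as near-identical pairs, and their single values are uncertain. Cluster 2 also listed 5 of 8 neutrophil genes (adjusted p = 0.00724), of which 0 were raised, with Mmp9 at 52.9, Il1b at 9.15 and S100a8 at 5.54 in the authors' deposited table. Among the largest folds were those of the bile salt exporter Abcb11 (647.4), Mug1 (189.3), Skint8 (172.3) and Trim29 (169.8) in cluster 1 of the authors' deposited table. By p these genes stood far from first, at positions 202 to 379 of the 1161 genes listed in cluster 1. For cluster 2 the largest folds were those of Fate1 (449.9), Caps2 (121.0), the mast cell protease Mcpt9 (92.8), the class II transactivator Ciita (92.3) and Uts2 (81.8) in the authors' deposited table. By p they stood at positions 347 to 604 of the 1661 genes listed there.

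A set of 14 genes of gastric lineage, stem cells and tumor biology was followed in every cluster. The mucins Muc5ac and Muc2 and the intestinal transcription factor Cdx2 were listed in 0 clusters, which for a table of folds above 1.5 does not show that they were not expressed. Prom1, the gene of the stem cell marker CD133, was raised in clusters 3, 5, 6 and 9, at 2.14, 2.65, 2.97 and 2.09 in the authors' deposited table. It lies on chromosome 5 from 43993620 to 44102032. The trefoil factor Tff2 was raised in clusters 3, 6, 7 and 9 at 2.36, 3.66, 2.22 and 2.18 in the authors' deposited table. The proliferation marker Mki67 was raised in clusters 6, 9 and 11 at 4.70, 2.89 and 2.30 in the authors' deposited table, and Gkn1 in clusters 6 and 9. The adhesion receptor Cd44 was raised in cluster 8 alone, at 2.001 in the authors' deposited table, and was listed without being raised in clusters 4 and 5 at 1.68 and 1.66. Krt8 was raised in cluster 9 at 2.01 and listed below a fold of 2 in clusters 2, 3, 6 and 7 in the authors' deposited table.

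Vimentin (Vim), an intermediate filament of mesenchymal and immune cells, was raised in clusters 4 and 11 at 2.29 and 2.43 in the authors' deposited table, and listed at 1.76 in cluster 7 and 1.85 in cluster 8. The Wnt target and stem cell receptor Lgr5 was raised in the fibroblast-like cluster 11 at 10.2 in the authors' deposited table, and listed without being raised in clusters 5 and 6 at 3.501 and 1.89. The kinase Dclk1, a marker of tuft cells, was raised in clusters 3 and 11 at 3.13 and 2.31 in the authors' deposited table and was not raised in cluster 1 at 4.02. The mucin Muc6 was raised in the macrophage-like cluster 4 at 7.76 in the authors' deposited table, and was listed but not raised in clusters 8 and 9 at 3.16 and 1.57.

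**Figure D3:**
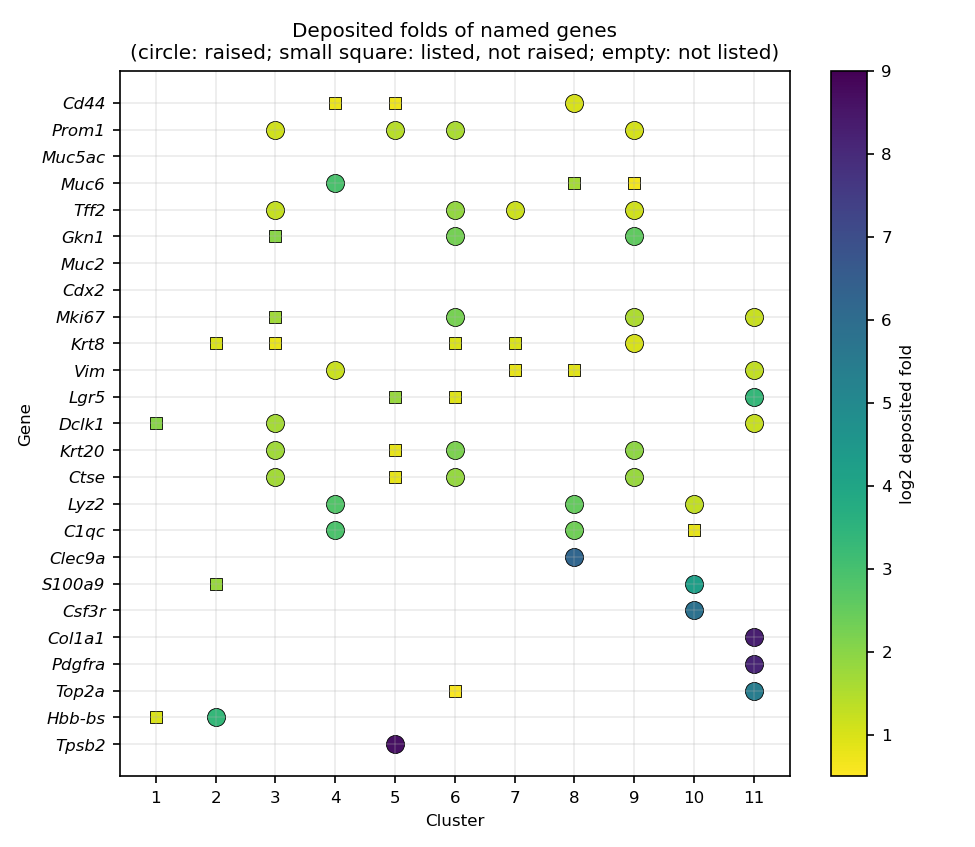
Deposited folds on a log2 scale (colour) of fixed genes and further marker genes (vertical axis) in the 11 clusters (horizontal axis). Large circles are raised genes, small squares are listed genes that were not raised, and an empty place is a gene that the table does not list there; Col1a1, Pdgfra and Top2a are raised in cluster 11 and Gkn1 in clusters 6 and 9.

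A short list can lack a call in a large cluster by its size alone. Of the 39 lists tested, 18 had no call in any cluster on listed members. Those of stem and dysplastic cells, tuft cells, squamous epithelium, smooth muscle, endothelium, ciliated or neural cells, heat shock, hypoxia and glycolysis, MAPK feedback, Wnt targets, Notch, nuclear-retained RNA and mucin glycosylation passed neither on listed nor on raised members. Their smallest adjusted p on listed members ran from 0.13 for hypoxia and glycolysis to 1 for smooth muscle. Against random lists of equal size, which weigh the size of folds, some of them did pass. Tuft cell genes in cluster 6, with 6 of 10 raised, lay at the percentile 100 for the median, 99.96 for the mean and 99.68 when matched. Squamous epithelial genes in cluster 3, with 2 of 8 raised, lay at 99.36, 99.76 and 99.66, and in cluster 6, with 3 raised, at 80.63, 99.66 and 99.26. Endothelial, stem and dysplastic, MAPK feedback and smooth muscle genes reached 99 by a mean alone, in clusters 1 and 2, 5, 5 and 11, and the tuft list did so in cluster 3. Such a mean can rest on few members. The endothelial list in cluster 1 had 1 of 8 listed, Pecam1, which was not raised. By the matched mean the fibroblast list also reached 99.81 in the macrophage-like cluster 4, with 2 of 11 listed. Of the 18 lists, the other 5 passed on raised members in 1 cluster or more. Cholesterol synthesis was one, with 7 of 11 raised in cluster 6 (adjusted p = 0.0294), led in the authors' deposited table by Sc5d at 4.57, with Fdft1 at 2.69. Cluster 9 had 6 of 11 raised without a call (adjusted p = 0.321, exact hypergeometric test). Intestinal absorptive genes were another, with 3 of 5 raised in cluster 3 (adjusted p = 0.0103), where the actin-bundling gene Vil1 was at 8.40, Krt20 at 3.28 and Lgals4 at 2.68 in the authors' deposited table. They are not particular to cluster 3. Without a call, 4 of 5 were raised in cluster 9 and 3 of 5 in cluster 6 (adjusted p of 0.179 and 0.373, same test), where more genes are raised. The remaining ones were the mast cell, oxidative phosphorylation and glutathione lists given above.

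Another 6 lists had fewer than 3 members in the table and were not tested. No mitochondrially encoded gene was named. For chief cells the transcription factor Bhlha15 was raised in cluster 9 at 2.57 in the authors' deposited table. For parietal cells the potassium channel Kcnq1 was raised in clusters 3, 6 and 9 at 2.95, 2.45 and 3.04 in the authors' deposited table, and Vegfb was raised in 0 clusters. For enteroendocrine cells the serotonin synthesis enzyme Tph1 was raised in clusters 6 and 9 at 4.24 and 4.60 in the authors' deposited table. Histidine decarboxylase (Hdc), of the same list, was raised in the neutrophil-like cluster 10 at 39.4 in the authors' deposited table. That cluster listed 0 of 9 general epithelial genes, so Hdc alone does not point to enteroendocrine cells there. The Paneth cell gene Lyz1 was raised in cluster 4 at 17.5 in the authors' deposited table and is a close copy of Lyz2, so its value is uncertain; Habp2 was not raised. The immunoglobulin gene Ighm was raised in clusters 4 and 10 at 2.97 and 16.7 in the authors' deposited table.

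The second question was which clusters resemble each other. Of 55 pairs of clusters, 9 shared more raised genes than the product of their list sizes gives. Clusters 8 and 10 shared 156 raised genes against 57.1 expected, a ratio of 2.73, and clusters 4 and 8 shared 579 against 216.5, a ratio of 2.67. The epithelial clusters 6 and 9 shared 1697 against 987.3, a ratio of 1.72, and clusters 2 and 7 shared 31 against 18.1, a ratio of 1.71. Cluster 3 shared 161 raised genes with cluster 6 against 148.6 expected, a ratio of 1.08, and 182 with cluster 9 against 194.9, a ratio of 0.934. Its highest ratio was with cluster 7 (30 against 25.05, a ratio of 1.20), and it shared 0 with cluster 8 against 46.7. Its grouping with clusters 6 and 9 rests on the gene lists and not on shared raised genes. The median ratio over the 55 pairs was 0.424.

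Across the genes listed in both clusters of a pair, log2 folds correlated weakly, with Pearson's r between −0.322 and 0.121 and a median of −0.0773. The highest was that of clusters 6 and 9 (0.121, Spearman's rho 0.175, 4071 genes), followed by clusters 4 and 8 (0.11, rho 0.164, 2433 genes). Genes are not independent replicates, and each cluster may be part of the reference of the others. In simulated clusters with no shared raised genes r ran from 0.177 to 0.625, all above the observed values, and the median ratio of shared to expected genes was 1.06 against the observed 0.424. That simulation did not resemble the table, so it gives no chance level for either quantity, and none is given here.

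**Figure D4:**
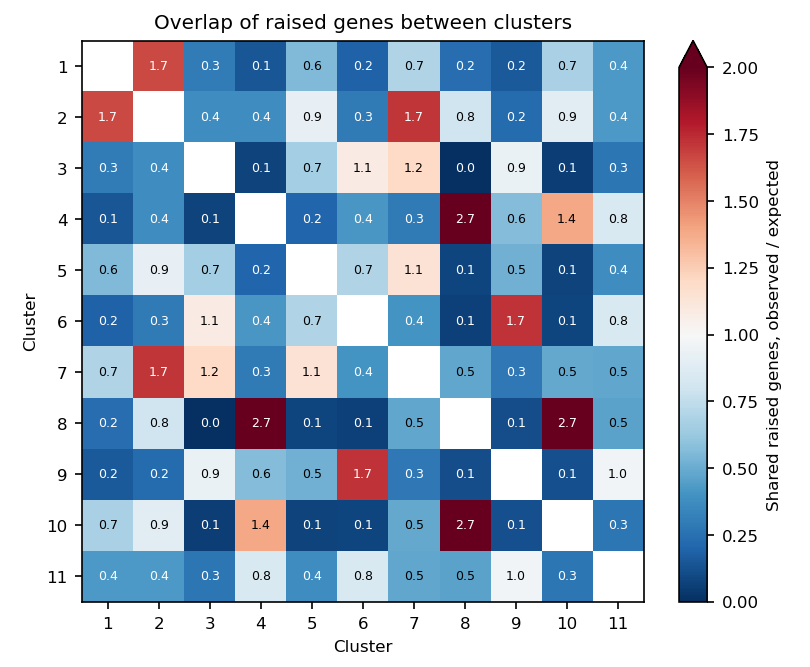
Ratio of shared raised genes to the number expected from list sizes, for each pair of the 11 clusters (both axes). Red is above 1 and blue below; the ratios of clusters 8 and 10 (2.73) and of clusters 4 and 8 (2.67) lie above the colour scale's top.

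The third question, how the cystic and the tubular tumor differ, could not be put to these values, because no column of the table names a tumor type. The types were also sampled at different times, 10 and 13 weeks, with 1 library each.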

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

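Counting genes at a fold of at least 2 whatever the p, and testing raised members at a fold of 2, were chosen after the data were seen. The cause of each change was not tested, except that stricter thresholds keep fewer genes by construction. Of the 37 calls for lists, 9 held under every alternative. Raised genes at a fold of 3 numbered 352 in cluster 2, 2220 in cluster 4, 2194 in cluster 6, 368 in cluster 7 and 2578 in cluster 9. At a p of 0.001 there were 139 in cluster 1, 227 in cluster 2, 144 in cluster 3, 368 in cluster 5, 2129 in cluster 6, 218 in cluster 7, 458 in cluster 8 and 406 in cluster 10. Adjusted p gave 181 in cluster 3, 520 in cluster 5 and 683 in cluster 8. Whatever the p, 1035, 1353, 4025, 2977, 1856, 3719 and 2907 genes reached a fold of 2 in clusters 1, 2, 3, 5, 7, 8 and 10. A fold of 1.5, or leaving out ribosomal and predicted genes, kept all 11 counts within 1.5 times. Lists with a call fell to 16 on raised members at a fold of 3, 22 without ribosomal and predicted genes and 21 without the largest member. The ribosomal list, with a call in clusters 3 and 7, could not be tested without ribosomal genes, so that part of the fall is by construction. For erythroid genes in cluster 1, raised members gave adjusted p of 0.545, 0.623 and 0.52 at folds of 1.5, 3 and 2, and percentiles were 98.57 for the mean and 97.47 when matched. Surface mucous genes in cluster 3 had an adjusted p of 1 at a fold of 3 and 0.0662 without the largest member, with percentiles of 97.37 (median), 86.72 (mean) and 92.25 (matched). In cluster 9 they moved past the threshold, at 0.0103 on raised members at a fold of 2 (0.054 at 1.5 and 0.0536 at 3) and percentiles of 99.93, 99.89 and 99.98. General epithelial genes in cluster 5 had adjusted p of 0.389, 1 and 0.353 on raised members at folds of 1.5, 3 and 2, 0.073 without ribosomal and predicted genes, 0.136 without the largest member, and percentiles of 92.92 (mean) and 61.7 (matched). In cluster 9 these were 1 and 0.834 at folds of 3 and 2, 0.068 and 0.102, with percentiles of 89.68 (median), 61.76 (mean) and 29.42 (matched). Ribosomal genes in cluster 7 had an adjusted p of 1 at a fold of 3 and percentiles of 100 (median), 88.23 (mean) and 0 (matched). Their matched percentile was 0 in each of the 11 clusters, so it says nothing particular about cluster 7. Spearman's rho for clusters 4 and 8, 6 and 9, and 3 and 9 was 0.164, 0.175 and 0.0613, and for 3 and 6 it was 0.0416 against r of −0.00914. Over genes raised in either cluster r was 0.00945, 0.0041 and −0.109 for 4 and 8, 6 and 9, and 3 and 6, and −0.0984 against 0.0087 for 3 and 9. The 100 genes of largest fold shared 0 in these 4 pairs, as in all 55, with 0.546 expected. The first 100 by p, a choice made after the data were seen, shared 64, 32, 49 and 15 for 4 and 8, 6 and 9, 3 and 6, and 3 and 9, ratios to the expected number of 117.2, 58.6, 89.8 and 27.5. The expected number is for random draws, which the first genes by p are not. Of the first 100 by p, 44 in cluster 3 and 26 in cluster 6 had ribosomal names. Clusters 3 and 7 shared 34, so these ratios do not measure how alike 2 clusters are. Limiting folds between tumor types was not run, since no column names a type. Depth limits all of this in an unknown degree, because cells per cluster and counts per cell are not given in the sources used here.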

Other observations

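The wider lymphoid list and the markers of unrelated types were written before their tests. Chosen only after results were seen were the test of the wider list in cluster 8, the chance of so few raised members of that list in cluster 10, the use of matched percentiles to judge the T and NK pattern in cluster 10, and the reading of the matched percentile in cluster 11 as undecided.

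A wider list of 19 named lymphoid genes outside the fixed T and NK list had 8 raised members in cluster 8, against 1.21 expected (one-sided exact hypergeometric p = 1.06e-05). The fixed T and NK list did not pass there, with 5 of 7 listed (adjusted p = 0.148) and 2 raised (adjusted p = 0.391), though its mean log2 fold lay at the percentile 99.93 of random lists. The 8 raised members of the wider list included the kinase Lck at 31.9, the gamma-delta T cell receptor gene Trdc at 29.3 and the interleukin-2 receptor chain Il2rb at 19.6 in the authors' deposited table. Also raised were Ltb at 20.4, Cd2 at 12.7, Ccl5 at 7.89 and Ptprcap at 2.704 in the authors' deposited table. The wider list had 4 raised members in cluster 4 against 3.53 expected, 2 in cluster 5 against 0.821, 2 in cluster 9 against 5.05, 1 each in clusters 6 and 7 against 3.85 and 0.649, and 0 in each other cluster. The label's strain, NuJ, is a name used for athymic nude mice, which form few mature T cells.

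The raised protein-coding genes of cluster 1 had a median genomic length of 44.7 kb, against 20.2 kb in cluster 7 and 27.4 kb in cluster 6, the next longest. Of the 333 raised genes of cluster 1, 0 had a name that begins like a ribosomal protein gene, against 78 of 626 in cluster 7. Names were matched at their start only, so pseudogenes are counted too. Cluster 7 had 39 raised pseudogenes with a ribosomal parent in the name. By p, cluster 1 began with the interferon-inducible gene Trim30a at 4.21 and cluster 2 with the translation factor Eef1a1 at 1.76 in the authors' deposited table. Trim30a was also raised in cluster 2 at 3.01 in the authors' deposited table.

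In cluster 7, ribosomal protein genes and their pseudogenes were raised together. A mixture of epithelial and fibroblast cells was predicted to list leaders of both. Of the first 50 non-ribosomal genes of cluster 11, 1 was listed in cluster 7 against 6.05 expected, a ratio of 0.165. For cluster 6 it was 18 of 50 against 6.05, a ratio of 2.97 (one-sided exact hypergeometric p = 1.13e-05). Cluster 11 may be part of the reference, so a minority of fibroblasts could leave its leaders unlisted in cluster 7. The expected numbers are also for random draws, which the leaders of a cluster are not. The counts therefore show many leaders of cluster 6 in cluster 7 but cannot decide on a mixture with fibroblasts. Reads shared between ribosomal genes and their pseudogenes may account for part of the pattern. The parent gene was listed for 25 of 39 raised ribosomal pseudogenes (64.1%), between the bounds of 80% and 50% set beforehand, and cluster 7 listed 64.5% of all 93 ribosomal protein genes, so this explanation cannot be told apart from a plain rise of the genes. No biological explanation was tested.

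In the neutrophil-like cluster 10, 5 of 7 T and NK genes were raised, namely Cd4, Cd3e, Gzma, Ncr1 and Nkg7. Lymphocytes grouped into the cluster would also raise the wider lymphoid list, and 0 of its 19 genes were raised against 0.93 expected (one-sided exact hypergeometric p = 1). The count met the bound set beforehand against lymphocytes, but chance gives as few with a probability of 0.385, so they are not excluded. Large folds of rarely detected genes may be a source: markers of unrelated types were raised for 2 of 27 genes, Pecam1 and Vwf, against 0 of 19 in the wider list (two-sided Fisher's exact p = 0.504). That p met the bound set beforehand for rare detection, but with 0 in the wider list this comparison could not have argued against it, so it decides nothing. The T and NK list lay at the percentile 100 of lists matched on the largest fold elsewhere. It was fixed beforehand, but it was taken up here because its members were listed in this cluster. Rare detection, lymphocytes and expression by other cells therefore cannot be told apart here. No biological explanation was tested.

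In the fibroblast-like cluster 11, 10 of 15 G2/M genes were raised. Large folds of rarely detected genes may account for them. The list's mean log2 fold was at the percentile 100 of random lists matched on the largest fold elsewhere, past the bound of 99 set beforehand against this explanation. That bound was wrong. The list was fixed beforehand, but it was taken up here because its members were raised in this cluster. The largest fold elsewhere also does not measure detection, so rare detection cannot be told apart from expression here. Whether the cells with cell-cycle genes are the cells with collagen genes also stays open, since the table gives no values per cell. No biological explanation was tested.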
